A study of Mus musculus with 17 samples.

How the data were processed

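Cortex of mouse embryos at embryonic day 14.5 was measured in 17 libraries. The 14 bulk RNA-seq libraries comprised 5 controls, 5 cortices of hGFAP-Cre;RosaFgf8 embryos and 4 cortices of hGFAP-Cre;RosaMEK1DD embryos. The 3 single-cell libraries comprised 1 control carrying floxed Map2k1 and Map2k2, 1 Emx1-Cre cortex mutant for both genes and 1 hGFAP-Cre;SmoM2 cortex. Groups and replicate numbers were taken from the sample labels. The series' design text gives the bulk numbers as mice per group.

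Per the labels' protocols, total RNA was isolated from dissected cortex, with kits of different makers named in different places, and the controls were littermates, without stating of which line. The sample descriptions and column names give all 5 controls the tag of the Fgf8 libraries, and the MEK1DD libraries a tag of their own. The bulk tables hold raw read counts per gene, as the file headers name them and as whole numbers with unequal totals show, deposited by the authors for each transgenic group together with the controls. The same tables hold FPKM values, the authors' counts scaled by exon length and mapped fragments, per the labels. They also hold the authors' own p-values, q-values and calls of each gene as up or down, per the file headers. The aligner, the counting program and the strand setting of the bulk data are not given in the sources used here, and the build named in the submitters' processing notes is mm10. The smallest total count of a gene over a table was 2. The 3 single-cell matrices hold UMI counts per gene and barcode, and per the file headers they were written by Cell Ranger 5.0.0, a program that the submitters' processing notes also name. Per the labels' protocols the cortex was dissociated with papain, captured on a 10x Genomics Chromium instrument and sequenced on either of a pair of Illumina instruments, without stating which library was run on which.

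The bulk tables listed 21225 and 21110 genes, with 20604 in common. No shared gene had a control count that differed between the tables, so the control libraries are the same in both and all 3 groups could enter a single fit. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and glmQLFit with glmQLFTest gave two-sided p-values adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Each transgenic group was fitted with the controls alone, and the difference between the transgenic groups was a contrast in a fit of all 3. Every adjusted p given for a gene is from this test unless another tool is named, and fold changes are log2 values with their standard error (SE) unless a fold is written. Group levels are means of the deposited FPKM values with their SD. A fold against a group whose libraries all had a count of 0 was computed against a floor of 3 counts per library, or over the class in single cells.

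A set of 32 gene lists of pathways, cell types and cell cycle phases was fixed before the data were examined, as were the tests, the rule for named genes and most of the alternatives. Lists with at least 5 measured members, 31 in each comparison, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated for each list. A further list had 4 measured members and was not tested. Named genes were the transgenes and targeted genes, 18 focal genes of the pathways under study, the 8 highest and 8 lowest fold changes among called genes with a mean above 1 FPKM in either group and replicate values that did not overlap, and up to 4 members of each list with the lowest p. In radial glia-like cells, the 8 highest and 8 lowest ratios were taken among genes with at least 50 CPM and 20 counts in either library and a ratio of at least 2-fold, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes. Predicted gene models were left out. A few further list members, most of them moving against their list, were chosen after their values were seen. Some named items are not reported here.

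In the single-cell libraries, cells with 750 to 5000 genes and under 10% mitochondrial counts were kept, which is the filter the series states. Counts were scaled to a common total per cell and log transformed, and 2000 variable genes were chosen with scanpy 1.11.5 in Python 3.11.15, leaving out sex-linked, mitochondrial and haemoglobin genes. Scores of S and G2/M genes were regressed out within each library. A graph of shared neighbours, from 15 neighbours in 30 principal components, was clustered jointly for the 3 libraries by the Leiden method at resolution 1 in igraph 0.11.9. A cluster took the name whose fixed markers had the highest mean level relative to the other clusters of the same library. Where other names scored within 0.15 of the highest, the name with most markers among the 10 leading genes was used, with leading genes ranked by fold with a pseudocount of 50 CPM. A cluster stayed unnamed with under 3 markers at 10 CPM, with more leading genes of another class than of its own, or with no leading gene of its own class. These rebuilt classes are not the authors' cell types.

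The markers and the cell filter were fixed before the data were examined, but the rest of the clustering and naming was not. The regression of cell cycle scores, the margin of 0.15, a condition of 10% haemoglobin counts for an erythroid name, the pseudocount of 50 CPM and the rule on clusters with no own marker were each added after named clusters had been looked at. A pseudocount of 10 CPM was tried first and left a large group of neurons unnamed, and without the margin a SmoM2 cluster with radial glial markers had been named after the oligodendrocyte lineage. The neighbour graph of an earlier version gave different clusters on different processors and was replaced by one that does not. That version had given a higher control radial glia-like share, outside the present counting interval. The radial glia-like share was chosen to lead the shares after the intermediate progenitor-like share was seen to move between settings. Each of the choices on naming and on the cell cycle was undone in turn as an alternative, apart from the haemoglobin condition.

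Doublets were scored by a re-implementation of the Scrublet method. The method's own threshold had marked no cell of the control library, so the cells with the highest scores were marked up to an expected 0.8% per 1000 cells. The marked shares of 6.17%, 4.19% and 8.19% in the control, MEK mutant and SmoM2 libraries therefore follow from the cell numbers and are no measurement. Marked cells stayed in the main results, and their removal was an alternative. With 1 library per group there is no test between groups. Shares of cells have exact binomial 95% intervals, summed counts exact Poisson intervals and ratios exact conditional intervals, and the median of a list has an interval from 1000 Poisson draws. All of them cover counting error only. A list of members at 10 CPM or more is described by the percentile of its median among 10000 random lists of the same size, matched on mean expression in 20 bins. Free RNA from lysed cells was not removed from the counts.

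Each bulk test was tested on simulated counts with 200 changed genes. For Fgf8 against control (14789 genes) it recovered 59.4% of genes changed 1.5-fold, 80% of those changed 2-fold and 93.9% of those changed 4-fold, with 7 unchanged genes called. For MEK1DD against control (14944 genes) the shares were 50.7%, 74.6% and 91.9%, with 7 unchanged genes called. For Fgf8 against MEK1DD (15308 genes) they were 59.4%, 76.6% and 95.5%, with 6 unchanged genes called. The real comparisons called 3526, 7907 and 8777 genes, far more than were changed here. Neither these shares nor the numbers of unchanged genes called therefore carry over to them. A correction for GC content and transcript length removes each library's trend with both by an offset. It was run on the same comparisons with a length trend simulated. The unchanged genes called fell from 3505 to 9, from 2932 to 8 and from 3585 to 17. Spearman's rho with length fell from 0.80, 0.78 and 0.79 to 0.145, 0.142 and 0.155. No GC trend was simulated, so the removal of GC trends was not tested in this way. In simulated single-cell libraries, 96.1% (7604 genes) and 95.8% (7968 genes) of the ratio intervals held the true ratio for the MEK mutant and SmoM2 comparisons. Transcript length and GC content came from GENCODE vM21 on mm10 and were known for 99.4% and 99.3% of the gene IDs in the bulk tables. Gene symbols and coordinates are those of the deposited tables.

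No replicate pair of a group agreed within sampling noise: the lowest chi-square per gene was 9.37, between MEK1DD replicates 2 and 3, and the highest 33.6. Xist and Ddx3y counts gave the libraries' sex, and the female libraries were control replicates 1 and 3, Fgf8 replicate 21 and MEK1DD replicate 4. Alternatives for the bulk tests were DESeq2 1.42.0, other scalings, other filters on low values, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the study's stated rule of FPKM above 1 with an unadjusted p under 0.05, a 2-fold minimum, a joint fit of all groups, the replicate number as a block and leaving out each library in turn. Alternatives for the single cells were a stricter filter of 1000 genes and 5% mitochondrial counts, doublet removal, each library clustered on its own, resolution 2, and cells thinned to 2000 UMIs. Sex as a covariate, the GC and length correction, gene list tests without each library, clustering without the SmoM2 library and the use of resolution 2 for expression were added after the data were seen, as were the alternatives that undo choices of the cluster naming. No per-sample column of the tables was left unused.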

Results

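The data comprised bulk RNA-seq of 14 cortices and single-cell RNA-seq of 3 cortices from mouse embryos at stage E14.5, when the dorsal wall of the forebrain holds dividing radial glia, intermediate progenitors and young neurons. In the bulk series, hGFAP-Cre activated a Rosa26-targeted Fgf8 gene (Fgf8 cortex, n = 5) or a constitutively active form of the kinase MEK1 (MEK1DD cortex, n = 4), and the controls (n = 5) are described as littermates. The labels name all 5 control libraries as part of the Fgf8 set and do not tie any to a MEK1DD litter. The single-cell libraries were a control with floxed Map2k1 and Map2k2, which encode MEK1 and MEK2, a cortex in which Emx1-Cre removed both genes (MEK mutant library), and a cortex in which hGFAP-Cre activated SmoM2, a constitutively active form of the hedgehog transducer Smoothened (SmoM2 library). The study's title asks how ERK signaling acts on cortical radial glia. Total counts per bulk library ran from 14675991 to 17780081 in controls, 15702681 to 17624096 in Fgf8 cortex and 15490646 to 16248593 in MEK1DD cortex. All barcodes before the cell filter held about 29373000, 28381000 and 99984000 UMIs in the control, MEK mutant and SmoM2 libraries. The cells kept had medians of 2777, 3694 and 8502 UMIs per cell.

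Fgf8 cortex against control addressed what added FGF8 does to the cortex. Fgf8 itself (chromosome 19, 45736798 to 45742915) averaged 7.31 ± 1.57 FPKM (SD, n = 5) in Fgf8 cortex and 0.335 ± 0.316 FPKM (n = 5) in controls. Targets and feedback regulators of ERK signaling rose, with Etv4 at 23.4 ± 1.49 against 0.525 ± 0.140 FPKM and Spry2 at 71.8 ± 5.90 against 6.11 ± 0.686 FPKM. Genes of the oligodendrocyte lineage and of ventral telencephalic progenitors rose too, with Olig1 at 131 ± 29.9 against 0.426 ± 0.147 FPKM. Eomes, a transcription factor of intermediate progenitors, fell to 19.2 ± 3.14 from 46.5 ± 2.31 FPKM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3526 of 14789 genes changed, 1900 higher and 1626 lower, and 667 of them changed at least 2-fold (472 higher, 195 lower).

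Of 21 measured ERK pathway targets and feedback regulators, 17 rose and 1 fell (18 and 1 adjusted over the list alone), and the list was higher by camera (adjusted p = 9.42e-15, and adjusted p = 0.00255 with an estimated correlation). The log2 fold change was 5.48 ± 0.14 (SE) for Etv4 (adjusted p = 4.48e-10), 3.55 ± 0.09 for Spry2 (chromosome 14, 105891949 to 105896819) and 2.33 ± 0.08 for Dusp6, a phosphatase of ERK. Fosl2, the member that fell (-0.46, adjusted p = 0.00603), encodes an AP-1 subunit and was named after its value was seen. Of 10 rostral patterning genes, 9 rose (9 adjusted over the list alone, with 1 lower; camera adjusted p = 1.35e-10, and adjusted p = 0.00516 with an estimated correlation), among them Sp8 (2.47) and Mest (2.78). Etv1, Etv4, Etv5, Spry1, Spry2 and Dusp6 belong to this list and to the ERK list. Of 14 caudal and cortical hem genes, 5 fell (8 adjusted over the list alone; camera adjusted p = 0.00123, lost at adjusted p = 0.516 with an estimated correlation), including Nr2f1 (-1.0).

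All 7 measured ventral telencephalic progenitor genes rose (7 adjusted over the list alone; camera adjusted p = 2.7e-09, and adjusted p = 0.017 with an estimated correlation). Among them were Gsx2 (6.26 ± 0.47, or 7.16 without control replicate 5) and Helt (7.03 ± 0.57, or 8.16 without control replicate 2). Of 8 oligodendrocyte lineage genes, 7 rose (7 adjusted over the list alone; camera adjusted p = 4.93e-09, and adjusted p = 0.0135 with an estimated correlation), including Olig2 (5.82 ± 0.29) and Egfr (2.48 ± 0.26). Olig2 is a member of both lists. Of 14 interneuron genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.000501, lost at adjusted p = 0.475 with an estimated correlation). Dlx2 (2.85) and Dlx5 (3.00) rose, and the receptor gene Erbb4 was among the lower ones (-0.83, adjusted p = 0.0168).

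Of 10 outer radial glia genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.000389, lost at adjusted p = 0.128 with an estimated correlation). Hopx rose to 57.2 ± 9.37 from 5.21 ± 1.03 FPKM and Tnc, an extracellular matrix gene, by 3.27, while Fam107a fell (-2.11). Of 13 intermediate progenitor genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 5.95e-05, lost at adjusted p = 0.298 with an estimated correlation). Eomes (-1.28 ± 0.11), Neurog2 (-1.42) and Neurod4 (-2.02) fell, and Hes6 (0.50) and Insm1 (0.49) rose. Cell cycle genes were higher, with 17 of 20 G2/M genes (19 adjusted over the list alone) and 13 of 20 S phase genes (17 adjusted over the list alone) rising, such as Kif11 (0.64) and Rrm2 (0.86). The camera adjusted p values of 2.18e-07 and 1.18e-06 were lost at adjusted p = 0.298 and adjusted p = 0.46 with an estimated correlation. Pax6 fell (-0.62 ± 0.07) while the radial glia list, with 8 of 20 rising and 5 falling (9 and 7 adjusted over the list alone), did not pass (camera adjusted p = 0.106).

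**Figure D1:**
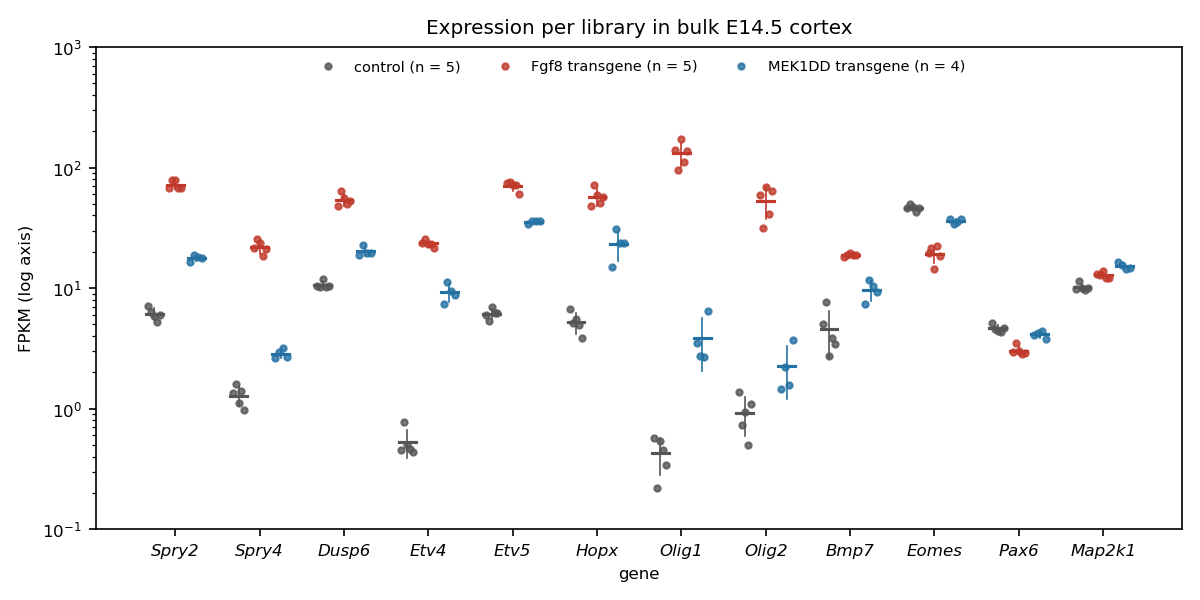
FPKM per library (log axis) of 12 genes in control (n = 5), Fgf8 (n = 5) and MEK1DD (n = 4) cortex, with points for libraries, horizontal lines for means and vertical lines for the SD. Etv4 averages 0.525 FPKM in controls, 23.4 in Fgf8 cortex and 9.25 in MEK1DD cortex.

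Among the largest increases were Gpr83 (8.07 ± 0.32), Cntn6 (7.45 ± 0.23) and Dio2, a deiodinase that activates thyroid hormone (5.56 ± 0.19). The largest decreases included Rbm20 (-4.38 ± 0.12), Prph (-4.35 ± 0.44), Cckar (-3.19 ± 0.15), Hey2 (-2.17 ± 0.21) and Prdm12 (-6.18 ± 0.54, or -7.12 without Fgf8 replicate 11). Pla2g16 (-2.48 ± 0.50) and Efhd1 (-2.25 ± 0.53) fell less without control replicate 4, to -1.68 (adjusted p = 2.13e-04) and -1.38 (adjusted p = 0.00143). Gli1 (-0.30, adjusted p = 0.341) and Ptch1 (-0.02, adjusted p = 0.945), targets of hedgehog signaling, did not pass. Bmp7, a BMP ligand, rose to 18.7 ± 0.518 from 4.54 ± 1.91 FPKM (2.04 ± 0.22, adjusted p = 5.16e-05). In the authors' deposited table, 2520 genes had a q-value under 0.05, and 2238 of these were also called here.

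MEK1DD cortex against control asked what active MEK1 does without added ligand, with the controls named as part of the Fgf8 set. Map2k1 (chromosome 9, 64185770 to 64253631), which encodes MEK1, rose to 15.2 ± 0.853 (SD, n = 4) from 10.2 ± 0.706 FPKM (n = 5). Fgf8 cortex, which does not carry this transgene, averaged 12.8 ± 0.691 FPKM (n = 5). The rise of Map2k1 is therefore no measure of the transgene alone. ERK pathway genes rose, with Etv5 at 35.5 ± 0.990 against 6.14 ± 0.596 FPKM and Etv4 at 9.25 ± 1.60 against 0.525 ± 0.140 FPKM. Hopx reached 23.2 ± 6.42 against 5.21 ± 1.03 FPKM and Tnc 48.7 ± 10.3 against 3.85 ± 1.11 FPKM. Most intermediate progenitor genes fell. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7907 of 14944 genes changed (3986 higher, 3921 lower), 1151 of them at least 2-fold (915 higher, 236 lower).

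Log2 fold changes in MEK1DD cortex followed transcript length (Spearman's rho across genes 0.409) and GC content (-0.350), where those in Fgf8 cortex gave 0.038 and -0.101. Once each library's trend was removed, 6797 genes were called, 2486 higher and 4311 lower, so that 36.6% of calls were higher against 50.4% before. The median log2 fold change then lay below 0 in every decile of length and GC content (-0.15 to -0.04). The balance of calls therefore moved together with a shift of all genes and is not read as a result. Genes are not independent replicates. Mitochondrial genes took 2.80% to 2.94% of counts in the 4 MEK1DD libraries, against 1.83% to 2.23% in controls and 1.92% to 2.31% in Fgf8 cortex.

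Of 21 ERK pathway genes, 12 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00505, lost at adjusted p = 0.105 with an estimated correlation). Etv4 (4.14 ± 0.17), Etv5 (2.53 ± 0.08), Spred3 (2.22) and Spry2 (1.54 ± 0.09) rose, and the list's median was 0.56 before and 0.59 after the length and GC correction. The members that fell, named after their values were seen, were Phlda1 (-0.42, or -0.26 corrected) and the immediate early genes Egr1 (-0.59, adjusted p = 0.0418) and Ier3 (-0.63, adjusted p = 0.0438). Egr1 lost its call without MEK1DD replicate 1 or 2 or control replicate 2, 4 or 5 (adjusted p = 0.0612 to 0.101), and Ier3 without MEK1DD replicate 3 or 4 or control replicate 1, 2, 4 or 5 (adjusted p = 0.0541 to 0.108) and after the length and GC correction (adjusted p = 0.243). Of 10 rostral patterning genes, 7 rose, with the same count adjusted over the list alone (camera adjusted p = 0.00109, lost at adjusted p = 0.105 with an estimated correlation), of which Etv1, Etv4, Etv5, Spry2 and Dusp6 are ERK list members too. Of 15 immediate early genes, 8 fell, with the same count adjusted over the list alone, including Jun (-0.89) and Jund (-0.96). That list's camera adjusted p = 0.00733 was lost with an estimated correlation (adjusted p = 0.653) and after the length and GC correction (adjusted p = 0.0736).

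Of 13 intermediate progenitor genes, 10 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00126, lost at adjusted p = 0.581 with an estimated correlation). Neurog1 (-1.56), Gadd45g (-1.33), Neurog2 (-0.65) and Eomes (-0.37 ± 0.06) fell. The member that rose, Elavl4 (0.55), encodes a neuronal RNA-binding protein, and was 0.04 after the correction. Of 12 deep layer and subplate genes, 8 rose, with the same count adjusted over the list alone (camera adjusted p = 0.00953, lost at adjusted p = 0.581 with an estimated correlation), including Tle4 (0.89) and Sox5 (0.79, or 0.34 corrected). After the correction 6 of them rose, and the list's median was 0.22 in place of 0.44. Of 14 pan-neuronal genes, 7 rose and 1 fell, with the same counts adjusted over the list alone, including Snap25 (1.63, or 1.04 corrected), while Tubb3 fell (-0.39), a call lost after the correction (-0.21, adjusted p = 0.074). After it 4 genes of the list rose, and its median was 0.17 in place of 0.29. That list's camera adjusted p = 0.0333 was lost with an estimated correlation (adjusted p = 0.835) and without MEK1DD replicate 1 (0.0573), control replicate 1 (0.0641) or control replicate 2 (0.0938).

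Of 10 erythroid genes, 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0102, lost at adjusted p = 0.581 with an estimated correlation and at 0.0534 after the length and GC correction). Haemoglobin took 0.067% ± 0.00675 (SD) of counts in MEK1DD cortex, 0.153% ± 0.0343 in Fgf8 cortex and 0.207% ± 0.0372 in controls. The outer radial glia list, with 5 of 10 rising and 2 falling, did not pass (camera adjusted p = 0.243), although Hopx (2.15 ± 0.20) and Tnc (3.66 ± 0.23) rose. Olig1 rose (3.16 ± 0.35) to 3.85 ± 1.80 FPKM, as did Dio2 (5.83 ± 0.18) and Grin2c, a glutamate receptor subunit (4.84 ± 0.19). Among the lowest, Lgi4 (-4.06 ± 1.41) rested on control replicate 4, with 5.16 FPKM there, a mean of 0.160 FPKM in the other controls and 0.0682 FPKM in MEK1DD cortex. It did not pass the filter on low counts without control replicate 1, 3, 4 or 5, and lost its call without MEK1DD replicate 1, 2, 3 or 4 (adjusted p = 0.0733, 0.0705, 0.0677 and 0.0752). Smoc2 (-3.08, adjusted p = 0.0258) lost it without MEK1DD replicate 1, 2 or 3 (adjusted p = 0.0665, 0.06 and 0.0669) and was -1.30 without control replicate 4 (adjusted p = 0.0142). Cd74 (-4.30 ± 0.84) was -3.44 without control replicate 4 and -5.01 without MEK1DD replicate 4. Hba-a2 and Rpl29, among the largest increases (6.65 and 5.47), have near-identical copies and are uncertain. In the authors' deposited table, 6505 genes had a q-value under 0.05, and 6044 of these were also called here.

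**Figure D2:**
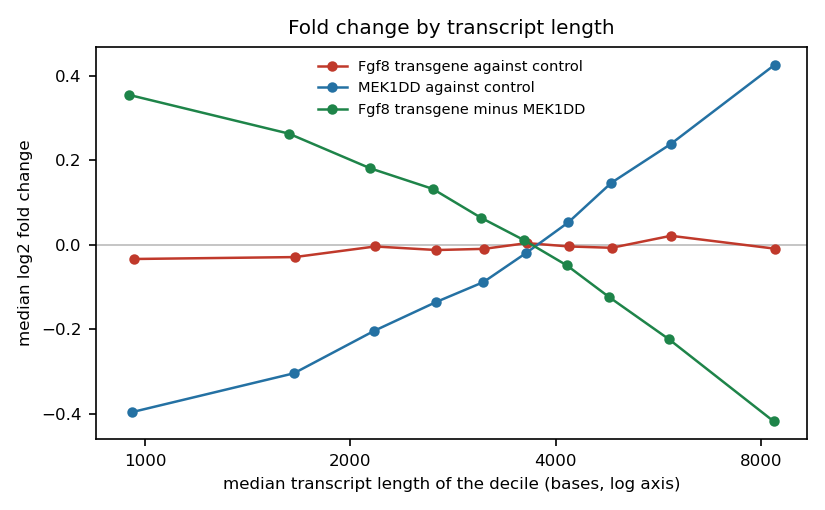
Median log2 fold change of genes in each decile of transcript length (log axis, bases) in the 3 bulk comparisons. Values rise with length in MEK1DD cortex, fall with length in Fgf8 minus MEK1DD and stay near 0 in Fgf8 cortex.

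**Figure D3:**
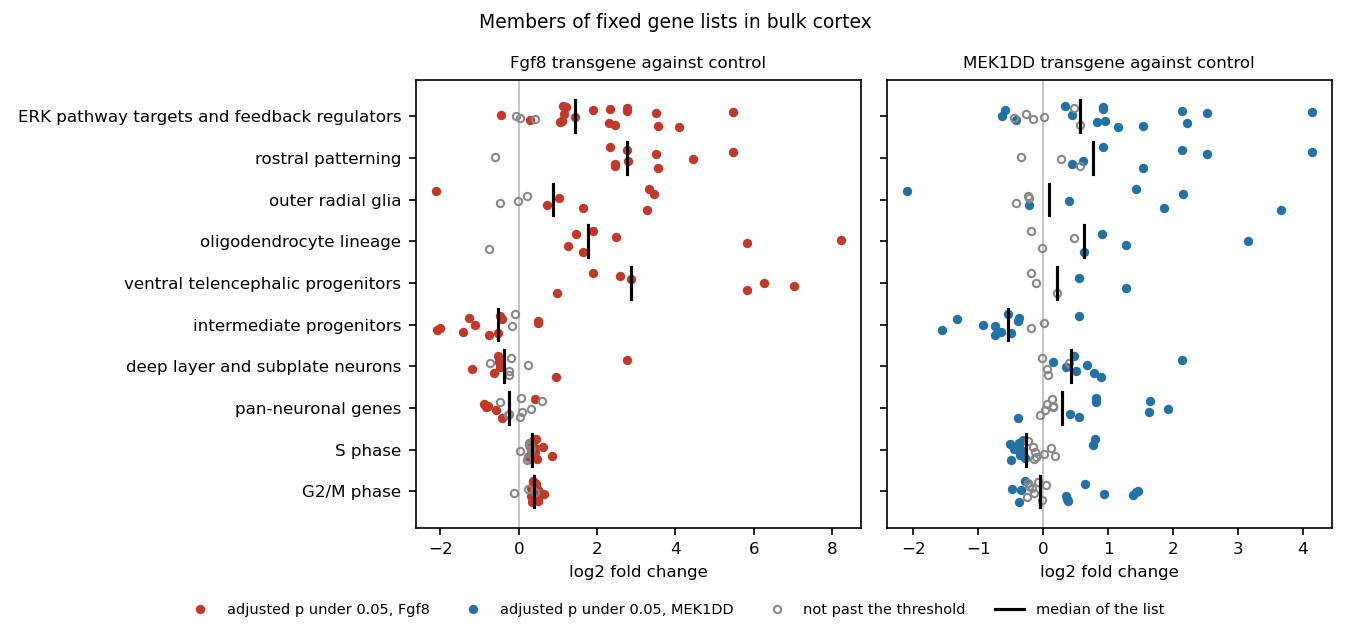
Log2 fold changes of the members of 10 gene lists in Fgf8 and MEK1DD cortex against control, with filled points for members at an adjusted p under 0.05, open points for the others and black lines for list medians. The horizontal axes of the panels differ, and the ERK list has a median of 0.56 in MEK1DD cortex.

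Fgf8 cortex was tested directly against MEK1DD cortex, since a call in one and not in the other is no difference. ERK pathway genes were higher in Fgf8 cortex, with Spry2 at 1.99 ± 0.08 (SE), Spry4 at 2.92 ± 0.13 and Dusp6 at 1.40 ± 0.08. So were ventral and oligodendrocyte lineage genes, with Olig1 at 5.06 and Dlx2 at 2.95, while neuronal genes were lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8777 of 15308 genes differed, 4426 higher and 4351 lower. After the length and GC correction, 8039 differed, 4835 higher and 3204 lower, or 60.1% higher against 50.4% before. Here too the balance moved with a shift of all genes, as every decile of length and GC content then had a median above 0 (0.01 to 0.16).

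Counts adjusted over the list alone were equal to those over all genes for each list given for this comparison here. Of 21 ERK pathway genes, 18 were higher and 1 lower (camera adjusted p = 4.16e-05, and adjusted p = 0.0419 with an estimated correlation). All 7 ventral progenitor genes were higher (camera adjusted p = 4.16e-05, lost at adjusted p = 0.129 with an estimated correlation), as were 7 of 9 oligodendrocyte lineage genes (camera adjusted p = 0.000357, lost at adjusted p = 0.129 with an estimated correlation). Of 14 pan-neuronal genes, 12 were lower and 1 higher (camera adjusted p = 0.000357, lost at adjusted p = 0.433 with an estimated correlation), including Snap25 (-1.56, or -1.02 corrected). Of 12 deep layer genes, 9 were lower and 1 higher (camera adjusted p = 0.0019, lost at adjusted p = 0.278 with an estimated correlation), including Sox5 (-1.43) and Bcl11b (-1.01). Eomes was lower (-0.93 ± 0.11), but the intermediate progenitor list, with 5 of 13 higher and 4 lower, did not pass (camera adjusted p = 0.985). Helt (8.80 ± 0.74) and Gsx2 (7.11 ± 0.69) were among the largest differences. Of the MEK1DD libraries, replicate 4 alone had counts of them (1 and 4), and without it Fgf8 cortex was at least 54.7-fold and 51.2-fold higher.

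Of 14641 genes tested in both comparisons with control, 757 were higher in both and 723 lower in both, where independent lists of these sizes give 489.93 and 434.68, and 20 simulations with unchanged groups gave 0. These simulations called at most 1 gene in a direction, so their 0 was fixed in advance. Both comparisons used the same controls. With the controls split between them, the medians of 20 splits were 496 higher in both and 413 lower in both, where independent lists give 321.63 and 259.15. Among the shared genes, 11 ERK pathway genes rose in both, including Etv4, Etv5, Spry2 and Dusp6, and 7 intermediate progenitor genes fell in both, including Eomes, Neurog1 and Neurog2. Of the outer radial glia genes, Hopx, Tnc, Acsbg1 and Ptprz1 rose in both and Fam107a fell in both. The covariance of fold changes was 0.141 against 0.0261 simulated from shared controls alone. Across genes, Pearson's r (0.403), Spearman's rho (0.252) and the share with the same sign (58.5%) lay below the simulated 0.476, 0.432 and 65.7%.

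The single-cell libraries asked what loss of MEK or active Smoothened does in radial glia. They have 1 library per group, so no difference between them has a replicate check. The stated filter left 7714, 5231 and 10243 cells of 8835, 5904 and 11891 barcodes, fewer than the 8649, 5811 and 11868 cells the series states. Radial glia-like cells were 8.32% (7.72 to 8.96, exact 95% binomial) of control, 6.96% (6.28 to 7.68) of MEK mutant and 7.30% (6.81 to 7.82) of SmoM2 cells, or 10.7%, 7.83% and 6.57% with the stricter cell filter. They lay in cluster 8 in the control and MEK mutant libraries and in cluster 11 in the SmoM2 library, and at resolution 2 the SmoM2 share lay above the control's. A ventral progenitor-like cluster held 302 SmoM2 cells (2.95%) and no cell of the other libraries. Other clusters split by library too, such as clusters 2 and 5, with 2251 and 1614 SmoM2 cells and none of the other libraries. The absence of control and MEK mutant cells from the ventral cluster therefore sets no limit on the share of such cells in those libraries. Shares of intermediate progenitor-like and neuron-like cells depended on how clusters were named. The first were 18.1%, 20.7% and 20.3%, but 4.77%, 3.5% and 20.3% when clusters were named by the highest score alone. The second were 59.7%, 57.2% and 51.1%, but 43.1%, 41.8% and 15.8% with another ranking of leading genes, so no difference is read from them. Unnamed clusters held 7.17%, 5.64% and 13.7% of cells.

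In radial glia-like cells of the MEK mutant library (364 cells, against 642 in control), ERK targets were lower, with Etv5 at 3 counts against 114 (log2 ratio -4.64, counting interval -6.94 to -3.06) and Spry2 at 11 against 139 (-3.05, -4.09 to -2.17). The outer radial glia gene Hopx had 3 against 222 (-5.60, -7.89 to -4.04). Etv4 had 0 counts against 18, with a counting interval that lay below -1.53, and the control was 3.94-fold higher when set against the floor of 3 counts. The ERK list's median over 8 members was -1.18 (-1.67 to -0.90), below all 10000 random lists, and was -0.14 (-0.30 to -0.05) in neuron-like cells. The erythroid list's median over 6 members was lower still, at -5.02 (-5.485 to -4.57), against -1.20 in neuron-like cells. In SmoM2 radial glia-like cells it was -4.54, so this control class held more erythroid RNA than the same class of either mutant library. The cause was not tested. Map2k1 (-0.12, -0.88 to 0.61) and Map2k2 (0.10, -0.10 to 0.29) check nothing, since these tags can lie outside the deleted part.

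Among genes at 50 CPM or more in either library, other low ratios were those of Scrn1 (-2.99), Fam181b (-2.40) and Mest (-2.18). Lamtor3, a scaffold of the pathway, was low too (-2.84), and as low in neuron-like cells (-3.12). The highest ratios among genes at this level included those of Sparc (2.24), Pttg1 (2.12), Lgals1 (1.77) and Nr2f1, a caudal patterning gene (1.45, 1.30 to 1.59). Eomes (0.70, 0.43 to 0.96) had an interval above 0. Pax6 (0.56) and Fabp7 (-1.82) are markers by which the class was named. Of 12 intermediate progenitor genes 8 were higher, with a median of 0.19 at percentile 98.7 of random lists, and of 20 G2/M genes 14 were higher, with a median of 0.16 at percentile 99.3. S phase genes had a median of -0.23 at percentile 0.05.

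**Figure D4:**
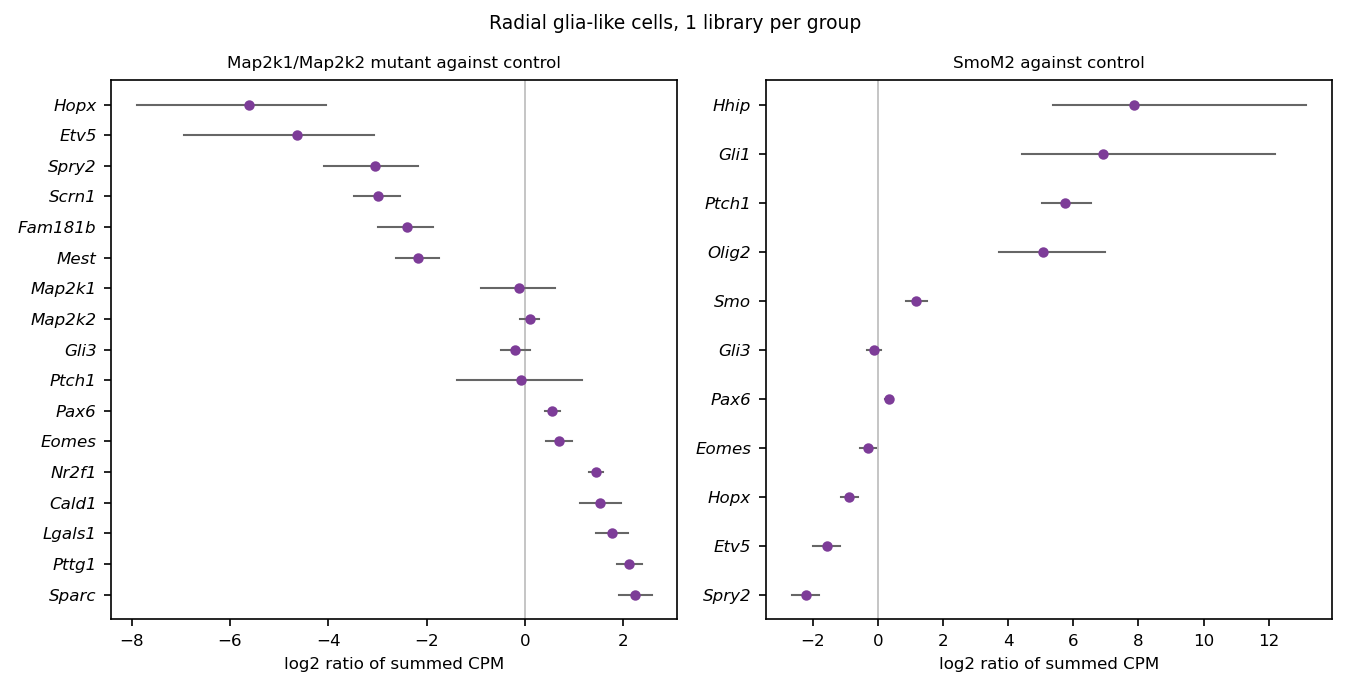
Log2 ratios of summed CPM in radial glia-like cells of the MEK mutant and SmoM2 libraries against the control library, with lines for 95% counting intervals and 1 library per group. Hopx lies at -5.60 in the MEK mutant library and Hhip at 7.85 in the SmoM2 library.

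In radial glia-like cells of the SmoM2 library (748 cells), targets of hedgehog signaling were higher. Hhip had 551 counts against 1 (7.85, 5.37 to 13.16), Gli1 285 against 1 (6.90, 4.41 to 12.21) and Ptch1 2030 against 16 (5.73, 5.03 to 6.54). Olig2 (5.07, 3.70 to 6.96) was higher, and Egfr had 132 counts against 0, 18.4-fold higher when set against the floor of 3 counts. Spry2 (-2.23, -2.66 to -1.80), Etv5 (-1.58, -2.0 to -1.17) and Hopx (-0.89, -1.14 to -0.63) were lower. Spry2 was nearly as low in neuron-like cells (-1.92, -2.11 to -1.73), while Etv5 was -0.59 and Hopx -0.21 in them. In radial glia-like cells the outer radial glia list had a median of 0.34 (0.24 to 0.93) over 5 members. The median over all genes there was 0.26, and ratios are to be read against it. The ERK list's median was -0.42 (-0.68 to -0.19), at percentile 0.16, while its mean was 0.18, and it was -0.69 (-0.88 to -0.50) in neuron-like cells. Intermediate progenitor genes had a median of -0.71 with 1 of 12 higher, and G2/M genes a median of 0.65 with 20 of 20 higher. This library was deeper per cell and had a median of 2.49% mitochondrial counts against 0.709% in the control, and the control library, which carries floxed MEK alleles, was not its own.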

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

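The tests of transcript length and GC content, of nerve markers, of library-wide differences and of other splits of the samples were chosen only after the results they bear on were seen.

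Fold changes in MEK1DD cortex followed transcript length and GC content. Bias of this kind as the whole cause of the 7907 calls is argued against by the 5371 (67.9%) that kept call and sign once each library's trend was removed. As the whole cause of the higher ERK list it is argued against by an adjusted p of 4.66e-05 after the correction, and of the higher pan-neuronal list by 0.021, although 4 genes of the latter then rose in place of 7, with a median of 0.17 in place of 0.29, and before it both calls were lost, at adjusted p = 0.105 and adjusted p = 0.835 with an estimated correlation. A difference in litter, preparation or RNA quality of the MEK1DD libraries stays open: mitochondrial counts were 2.80% to 2.94% in these libraries and 1.83% to 2.31% in the others, and Fgf8 minus MEK1DD followed length with a rho of -0.341 across genes, against 0.409 for MEK1DD, but the labels name no batch, all 5 controls are named as part of the Fgf8 set, and a difference between the sets is confounded with the MEK1DD transgene. An effect of active MEK1 on long transcripts was not tested and stays open too.

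Control replicate 4 held high levels of genes of Schwann cells, the glia of peripheral nerves. Of 19 measured markers of these cells, of which Pmp22, Mbp and Drp2 averaged above 1 FPKM in the other controls too, 18 were at least 2-fold above the next highest of the 14 libraries, with Pmp22 at 186 FPKM and Mbp at 22.3 FPKM. More oligodendrocyte lineage cells are argued against, since the median ratio of 5 genes of that lineage to the other controls was 1.09. Peripheral nerve RNA in this dissection is therefore a candidate explanation, and it bears on Lgi4 and on Smoc2, which was -3.08 in MEK1DD cortex and -1.30 without this library. It bears too on Sox10 and Egr2, members of the oligodendrocyte lineage and ERK lists. They had 11.8 and 2.24 FPKM in control replicate 4, against means of 0.0652 and 0.0393 FPKM in the other controls. Sox10 was not among the 5 lineage genes above. No other biological explanation was tested.

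The extreme ratios of radial glia-like cells, among genes at 50 CPM or more in either library, may belong to whole libraries. The 8 lowest of the SmoM2 library had a median of -2.83 in neuron-like cells and -2.64 in radial glia-like cells, in line with a difference of the whole library, such as preparation. For its 8 highest, which include Hhip, Ptch1 and the immediate early gene Egr1, the medians of 2.84 and 5.89 leave it open, as these genes were picked for their ratios in radial glia-like cells, and Hhip was 4.69 and Egr1 0.49 in neuron-like cells. So do -1.06 and -2.27 for the 8 lowest of the MEK mutant library. Lamtor3 (-3.12), Erdr1 (-1.88) and Mt3 (-1.82) were as low in neuron-like cells. Scrn1 (-1.09), Fabp7 (-1.03), Hopx (-0.94), Fam181b (-0.54) and Mest (0.08) were not. Erdr1 and Mt3 were also among the 8 lowest of the SmoM2 library. SmoM2 activity and loss of MEK in all cell types stay open as untested causes.

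Of 100 splits of the libraries in each comparison, the real one included, only the real one called as many genes. This is the lowest rank that 100 splits allow, and it argues against chance assignment of libraries. A litter or preparation difference that follows the groups was not tested by these splits. The real counts were 3526, 7907 and 8777 for Fgf8, MEK1DD and Fgf8 minus MEK1DD, and the highest of the other splits gave 2, 5089 and 6190. For Fgf8 minus MEK1DD, splits that only moved 1 Fgf8 library to the MEK1DD side called 4946 to 6190 genes. Apart from these and the real one, no split of that comparison called more than 3.

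Single libraries stood apart from their group in 18 of 123 groups of values (14.6%). Chance gives about 1 in 20 for independent, normally distributed values. Values of named genes in the same libraries are not independent, so no excess over chance is read from this share. The measure is the gap to the nearest library as a share of the group's range. Control replicate 4 was highest for Cd74 (0.962), Efhd1 (0.883), Kcna1 (0.725), Lgi4 (0.963), Pla2g16 (0.874), Rpl29 (0.780) and Smoc2 (0.972). Other controls were highest for Dusp6 (replicate 3, 0.864), Map2k1 (replicate 2, 0.828) and Pcdhgc5 (replicate 5, 0.718). Among Fgf8 libraries, replicate 27 was highest for Bmp4 (0.714) and lowest for Etv5 (0.710), replicate 21 highest for Cldn3 (0.849) and replicate 12 highest for Pax6 (0.796). Among MEK1DD libraries, replicate 4 was highest for Ccl27a (0.863) and lowest for Rpl29 (0.945), replicate 2 highest for Dusp6 (0.880) and replicate 3 lowest for Ptch1 (0.95).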

How the results depend on the processing

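Alternatives on sex, GC content and length, on gene lists without single libraries, on clustering without the SmoM2 library, on resolution 2 for expression and on each choice of the cluster naming were chosen only after the data were seen; the others were not. Counts of genes called in each comparison stayed within 1.5 times under every alternative except a 2-fold minimum, which by construction left 667 genes for Fgf8 and 1151 for MEK1DD. With an estimated correlation, 4 of 12 lists stayed called for Fgf8, 0 of 7 for MEK1DD and 1 of 12 for Fgf8 minus MEK1DD, where fry, which does not compare a list with other genes, called 14 for MEK1DD and 20 for Fgf8 minus MEK1DD. Counts shared by both transgenes fell by more, from 757 to 496 higher and from 723 to 413 lower, with the controls split, which leaves fewer samples in each test. For named genes, 929 of 962 values for Fgf8 and 167 of 174 for Fgf8 minus MEK1DD kept direction and call, while of 1055 for MEK1DD 59 lost the call and 8 reversed. Of values without single libraries, 808 of 830, 663 of 694 and 511 of 522 kept both, in the order Fgf8, MEK1DD and Fgf8 minus MEK1DD.

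Of the reversed genes, Gli3 in MEK1DD cortex and Hells and Ccne2 in Fgf8 minus MEK1DD had passed before, and the cause was not tested. After the length and GC correction, Map2k2 was 0.00 (0.00214) in Fgf8 cortex, Ptch1 -0.32, Gli3 -0.0163 (0.34 before) and Egfr -0.0832 in MEK1DD cortex, and Ptch1 0.28, Hells 0.16 and Ccne2 0.18 in Fgf8 minus MEK1DD (the last pair -0.54 and -0.39 before). On log2 FPKM, Ptch1 was 0.0017 and 0.0103 in Fgf8 cortex. Without single libraries, Fgf8 values ran from -0.068 to 0.0282 for Map2k2, -0.72 to 0.0744 for Bmp4 and -0.10 to 0.0938 for Ptch1, and MEK1DD values from -0.21 to 0.53 for Bmp4 and -0.0597 to 0.15 for Gli1.

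No label says that replicate numbers pair the bulk samples. Deviations of same-numbered libraries correlated at -0.199, 0.321, -0.146 and -0.0743, and only replicate 2 correlated best with its own number. So few libraries cannot exclude a pairing. With the number as a block, 6744 genes were called for MEK1DD, and 5273 with the length and GC correction. Control replicate 5 has no MEK1DD library of its number and was left out of these fits. The effect of the block therefore cannot be told from that of leaving out this library. With the block alone Bmp4 was -0.0159, and with the block and the correction Gli1 -0.0093, Ptch1 -0.35, Gli3 -0.0054 and Egfr -0.21.

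The radial glia-like share of the MEK mutant minus that of the control (-1.36 points) was -2.84 with the stricter filter and -2.57 in thinned cells, and lay below 0 under every alternative run. For SmoM2 (-1.02) it was -4.10 with the stricter filter and 0.70 at resolution 2, so its direction is not settled. None of the 4 choices of naming and cell cycle that were undone moved either share by more than its counting interval. The ventral cluster's share was 3.56 points in thinned cells, and the cluster took the name of the oligodendrocyte lineage by the highest score alone and with doublets removed. The intermediate progenitor-like difference of the MEK mutant (2.64) ran from -2.46, with each library on its own, to 5.18. The ERK list's median in MEK mutant radial glia-like cells was -0.87 with the stricter filter, and Eomes in SmoM2 (-0.31, -0.54 to -0.08) reversed to 0.92 in thinned cells and was below 0 under every other alternative run; the cause was not tested. Of named genes, 280 of 294 values for the MEK mutant and 245 of 274 for SmoM2 stayed within counting error, and 1, that of Eomes, changed sign. Depth limits genes of few counts, such as Map2k1 in MEK mutant radial glia-like cells (-0.88 to 0.61).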

Other observations

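The hypotheses on genes shared by both transgenes were written before their tests were run, although values of some members, such as Hopx, Etv5 and Spry2, and of the ERK list had already been seen.

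Members of other gene lists were called in both transgenic cortices by edgeR's quasi-likelihood test, which called 23.8% of all genes in Fgf8 and 52.9% in MEK1DD cortex. Of astrocyte lineage genes, 4 of 15 rose and 3 fell in Fgf8 cortex (5 and 4 adjusted over the list alone) and 7 of 14 rose and 1 fell in MEK1DD cortex, or 3 and 2 after the length and GC correction, with a median of -0.02 in place of 0.16. Bcan, Aqp4 and Aldh1l1 rose in both, with Bcan at 2.10 in Fgf8 and 1.36 in MEK1DD cortex. Aqp4 was 1.03 in MEK1DD cortex and did not pass after the length and GC correction (0.58, adjusted p = 0.062), and Aldh1l1 was 1.31 and did not pass without MEK1DD replicate 4 (adjusted p = 0.0558). Of 10 Notch genes, 5 fell and 2 rose in Fgf8 and 7 fell and 2 rose (7 and 0 corrected) in MEK1DD cortex, and the effectors Hes1 (-0.63 and -0.80) and Hes5 (-0.65 and -1.21) fell in both. Of 10 and 9 WNT targets, 4 and 2 fell, Axin2 (-0.64 and -0.54) and Nkd1 (-0.47 and -1.0) in both, and 1 rose in each, which was Znrf3 (0.57 and 0.95). None of these lists passed as a whole: camera gave adjusted p = 0.164 and 0.301 for astrocyte lineage, 0.166 and 0.175 for Notch and 0.322 and 0.47 for WNT genes. Where not stated, counts adjusted over the list alone were equal. Hes1 in both cortices, and Aqp4 and Aldh1l1 in MEK1DD cortex, were chosen after their values were seen.

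In Fgf8 cortex, 4 of 9 endothelial genes rose (5 adjusted over the list alone; camera adjusted p = 0.0197, adjusted p = 0.516 with an estimated correlation, and 0.0528 without control replicate 1). Of 9 Cajal-Retzius genes, 3 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.475 with an estimated correlation, 0.0528 without control replicate 1, 0.0629 without control replicate 2 and 0.0517 after the length and GC correction).

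In Fgf8 against MEK1DD cortex, 18 of 20 S phase genes were higher and 2 lower (camera adjusted p = 0.000149, adjusted p = 0.528 with an estimated correlation), and 9 of 11 rostral patterning genes were higher and 1 lower (camera adjusted p = 0.000973, adjusted p = 0.129 with an estimated correlation). Of 15 immediate early genes, 10 were higher (11 adjusted over the list alone; camera adjusted p = 0.00121, adjusted p = 0.378 with an estimated correlation). Of 10 Cajal-Retzius genes, 7 were lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.0238, adjusted p = 0.433 with an estimated correlation). Of 20 radial glia genes, 11 were higher and 2 lower (camera adjusted p = 0.0221, adjusted p = 0.55 with an estimated correlation), 7 of 10 erythroid genes were higher (camera adjusted p = 0.0238, adjusted p = 0.528 with an estimated correlation) and 6 of 12 upper layer genes were lower (camera adjusted p = 0.0287, adjusted p = 0.378 with an estimated correlation). The last 3 lists did not pass after the length and GC correction (adjusted p = 0.0864, 0.0961 and 0.131). Except where given, counts adjusted over the list alone were equal.

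Some lists that did not pass had a median, mean and test of different sign. In Fgf8 cortex, erythroid genes had a median of -0.42 and a mean of 0.25 with a test direction of lower, BMP targets 0.15 and 0.04 with lower, and p53 targets -0.0089 and 0.03 with higher. In MEK1DD cortex, G2/M genes had -0.05 and 0.22 with higher, striatal genes -0.05 and -0.0089 with higher, and meningeal genes -0.16 and -0.09 with higher. In Fgf8 minus MEK1DD, striatal genes had 0.10 and -0.09 with lower, thalamic genes -0.39 and -0.07 with higher and choroid plexus genes -0.48 and -0.30 with higher.

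A hypothesis was that genes raised by both transgenes depend on MEK and are lower in MEK mutant radial glia-like cells. Their median log2 ratio over 343 genes was -0.155, below random lists (-0.0135 to 0.0715), and 503 genes lowered by both had 0.128, above random lists (-0.00972 to 0.0542). Both are consistent with the hypothesis, in 1 library per group. Admixture of intermediate progenitor-like or neuron-like cells as the whole cause is argued against. The medians of -0.155 and 0.128 also lay outside random lists matched on the control library's ratios of radial glia-like cells to these classes (-0.0569 to 0.0393 and 0.0331 to 0.0978). Mixes by cell cycle phase or cortical region were not matched and stay open. In neuron-like cells the raised genes also had a low median (-0.069, random lists -0.0331 to 0.0172), so a difference of the whole library stays open. A further hypothesis, that the raised genes are lower in SmoM2 radial glia-like cells, was not borne out: their median was 0.547, above random lists (0.202 to 0.349).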
